A study of Mus musculus with 17 samples.

How the data were processed

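Livers of C57BL/6 mice, a common inbred laboratory strain, were studied after 10 weeks on a high-fat diet (HFD), in which fat supplied 60% of the calories, or a control diet (CD), in which it supplied 18%. The labels list 17 samples. Polyadenylated RNA was sequenced from 4 livers per diet, and chromatin immunoprecipitated with an antibody to histone H3 acetylated at lysine 9 (H3K9ac) from 3 livers per diet. A control-diet input library and 2 control-diet libraries of open chromatin (ATAC-seq) are also labelled. No column of the tables belonged to those 3 libraries, and they were not analysed here. Each library carries a letter within its diet: A to D for RNA in both diets, A, C and D for H3K9ac under CD, and A, B and D under HFD. Whether equal letters in the 2 assays mark the same animal is not stated in the labels, and neither are the hour of collection and the feeding state. The RNA column headings held numbers whose meaning is not stated. They were 528 to 551 with S56 to S59 under CD, and 435 to 505 with S60 to S63 under HFD. Anything that these numbers mark cannot be told apart from the diet.

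The authors deposited 1 table per assay. Per the file headers, the RNA table held raw read counts per gene, log2 FPKM values, and a log2 fold change, p-value and false discovery rate for HFD against CD. Per the file headers, the H3K9ac table held raw read counts per region in 1 set of regions common to all libraries, log2 CPM (counts scaled to library size), and the same kinds of p-value and log2 fold change, together with the distance of each region to the nearest transcription start site and the overlapping gene parts. The genome build was mm10, per the submitters' processing notes, and all coordinates are in that build. The aligner, the peak caller, the read counter, its use of strand and the authors' test are not given in the sources used here. Reads could be split between near-identical genes, so values of the Cyp2b, Cyp2c, Cyp2a, Cyp4a12, Ugt2b, Mup, Serpina and Hamp families are uncertain.

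The RNA table listed 12334 genes and 4999 blank lines, which were left out. The lowest mean count of a listed gene was 13.9, so genes with few reads were absent from the table and could not be tested. The H3K9ac table had 57571 lines for 57499 regions, of which 71 were listed more than once and were counted once. Gene names had become spreadsheet date numbers in 119 lines, and these lines were used without a gene name. All value columns were matched to a labelled library, and 0 were left unmatched.

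Total counts lay between 31802893 and 37596560 per RNA library and between 9255635 and 12149497 per H3K9ac library. A count of 3, taken as the floor, corresponded to 0.08 to 0.094 CPM in the RNA and 0.247 to 0.324 CPM in the H3K9ac. Counting intervals have a 95% confidence level and cover counting error only, since no molecular identifiers were reported. No 2 libraries were alike within sampling noise: the lowest chi-square per degree of freedom between libraries was 32 in the RNA and 1.5 in the H3K9ac.

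Diets were compared with edgeR 4.0.16 in R 4.3.3. Counts were scaled with TMM factors, filterByExpr was applied (it removed no gene and no region), and glmQLFit and glmQLFTest were fitted with diet as the only term, separately per assay. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes or all regions, with 0.05 as the threshold. Changes are log2 of HFD over CD with the standard error (SE) from the quasi-likelihood F statistic. Levels are CPM after TMM scaling, as mean ± standard deviation (SD) over n libraries. All adjusted p-values of single genes and regions come from this test. For log2 levels a prior count of 2 was used.

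A set of 34 gene lists (22 pathways and 12 cell types) was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, for lists with at least 5 measured members. Camera compares a list with all other genes, and its p-values were adjusted over the lists of an assay. For the H3K9ac, each gene was given 1 promoter-proximal region, the one with the highest mean signal among those within 1000 bases of a start site by the authors' distances. For regions of Csad and Rgs16 these distances ran from the middle of the region. Regions were 213 to 18730 bases long, so a long one could span a start site and still count as over 1000 bases away. Overlaps were tested with Fisher's exact test, two-sided. It counts genes or regions as independent units, which they are not, so its p-values and intervals do not cover the spread between livers. Correlations between the assays run across genes, which are not independent replicates, and are descriptions.

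The genes named follow a rule. In the RNA it took genes past the threshold whose HFD values all lay on one side of all CD values, at or above the median level: the 8 with the largest increase and the 8 with the largest decrease. Up to 4 members of each list with the smallest p, and 8 genes past the threshold in both assays, were added. In the H3K9ac it took the 6 largest increases and the 6 largest decreases under the same conditions, and the region of each gene named from the RNA. There were 513 RNA genes and 1116 regions to choose from; 15 RNA genes known only by clone names were left out. The groups, tests, gene lists, naming rule and alternatives were fixed before the data were examined, apart from those marked as added. The text says where a gene was named after its values had been seen.

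On simulated counts with the means, library sizes and dispersions of the RNA data over 12334 genes, 97% of 100 genes changed by log2 1 and 100% of 100 genes changed by log2 2, all at or above the median level, were recovered, with 5 false calls among 202. For the H3K9ac, simulated over 57499 regions, 36% of 100 regions changed by log2 0.5 and 86% of 100 changed by log2 1 at or above the median level were recovered, with 9 false calls among 131. None of 30 random lists was called in either assay (0 of 30). Genes were simulated independently, whereas the estimated correlation within real RNA lists reached 0.921 (MHC class II). The simulation therefore cannot show how often lists of correlated genes are called falsely.

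Alternatives were DESeq2 size factors, library totals, the DESeq2 1.42.0 Wald test, no filter, a filter at the median level, the letter as a block, leaving out each library, other thresholds, an estimated inter-gene correlation, fry, other promoter distances and other ways to relate the assays. Added after the data had been seen were a model with the level of endothelial marker genes as a term, and an odds ratio within 4 equal groups of regions by H3K9ac signal.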

Results

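The series addresses how H3K9ac, a histone mark found at active promoters, relates to transcript abundance in mouse liver after a high-fat diet. RNA was measured in 4 HFD and 4 CD livers, and H3K9ac in 3 and 3. Total RNA counts per library were 33004087, 35643097, 32632118 and 32924397 for CD A to D, and 37596560, 34572837, 32054730 and 31802893 for HFD A to D. Total H3K9ac counts were 11197235, 12149497 and 10080116 for CD A, C and D, and 11725503, 11222032 and 9255635 for HFD A, B and D. Correlations of log2 CPM between libraries ranged from 0.984 to 0.99 within CD, 0.97 to 0.99 within HFD and 0.957 to 0.98 between diets in the RNA. In the H3K9ac they ranged from 0.971 to 0.977 within CD, 0.971 to 0.979 within HFD and 0.966 to 0.973 between diets.

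The liver transcriptome differed between the diets, and among genes at or above the median level the largest increases were those of Cyp2b9 and Dbp and the largest decreases those of Csad and Ugt2b38. Dbp, a clock-controlled transcription factor, rose from 1 ± 0.425 to 95.1 ± 42.4 CPM (SD, n = 4 per diet, log2 change 6.57, SE 0.41, adjusted p = 2.45e-05). Csad, an enzyme of taurine synthesis, fell from 610 ± 89.3 to 35.1 ± 7.27 CPM (log2 change -4.12, SE 0.18, adjusted p = 3.51e-06). Cyp3a11, a major drug-metabolising cytochrome P450, fell from 3827 ± 606 to 619 ± 144 CPM (log2 change -2.63, SE 0.19, adjusted p = 6.28e-05). Cyp2b9, another cytochrome P450, had 3 counts over the 4 CD libraries and 6114 over the 4 HFD libraries, a ratio of 2080 with a counting interval of 711 to 10090 (adjusted p = 6.25e-06).

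Other genes with large increases were Mfsd2a, a lysolipid transporter (log2 change 4.37, SE 0.44), Rgs16, a regulator of G-protein signalling (4.28, SE 0.9), and Hamp2, a hepcidin gene (3.87, SE 0.63). The other hepcidin gene, Hamp, named after its values had been seen, fell (-1.37, SE 0.27, adjusted p = 0.0128). Per1, Usp2 and Ccrn4l rose by log2 3.66, 3.42 and 3.40. Decreases included Ugt2b38 (log2 change -3.88, SE 0.35), the immediate early gene Egr1 (-3.45, SE 0.55) and Pdk4, a kinase that restrains pyruvate oxidation (-3.06, SE 0.25). Serpina4-ps1, Cml5 and Fabp5, a fatty acid binding protein, had log2 changes of -2.75, -2.73 and -2.72. The call of Rgs16 was lost without CD A (adjusted p = 0.0563) and without CD C (adjusted p = 0.0564).

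By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 897 of 12334 genes passed the threshold, 448 higher and 449 lower in HFD, and 361 of them differed at least 2-fold. Of the 897, 874 had HFD values that all lay on one side of all CD values; over all genes 1761 did (14.3%, against 2.86% by chance). The count was 478 without HFD B, 563 without CD B, 584 without CD A and 586 without CD C, 1405 with DESeq2 and 543 with a filter at the median level, which tested fewer genes. With library totals it was 859, 367 higher and 492 lower, so the even balance of directions depended on the scaling. With the level of endothelial markers as a term, added after the data had been seen, it was 1585, and all 897 were kept. At the same threshold the authors' deposited values called 1252 genes, 626 in each direction, and all 897 were among them.

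Clock genes differed between the diets more than any other list by the number of members past the threshold. Of 18 members, 12 rose, 4 fell and 2 did not pass. Adjusted over the list alone, 12 rose and 5 fell. Per3 rose from 1.49 ± 0.243 to 24.4 ± 11 CPM (SD, n = 4, log2 change 4.04, SE 0.34, adjusted p = 0.000122), and Nr1d2, a repressor of the clock, from 32.6 ± 5.67 to 112 ± 15 CPM (log2 change 1.78, SE 0.15, adjusted p = 0.000122). Nfil3, a repressor of Dbp target genes, fell from 60.5 ± 5.63 to 18.3 ± 2.71 CPM (log2 change -1.72, SE 0.12, adjusted p = 6.21e-05). The clock activators Npas2 and Arntl fell by log2 changes of -4.08 (SE 0.41, adjusted p = 0.00031) and -2.56 (SE 0.29, adjusted p = 0.000609), and Cry1 by -1.28. Arntl and Cry1 were named after their values had been seen. All 16 called members had diets that did not overlap. The list had a median log2 change of 1.36 (camera adjusted p = 8.23e-05, and adjusted p = 0.118 with an estimated correlation).

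**Figure D1:**
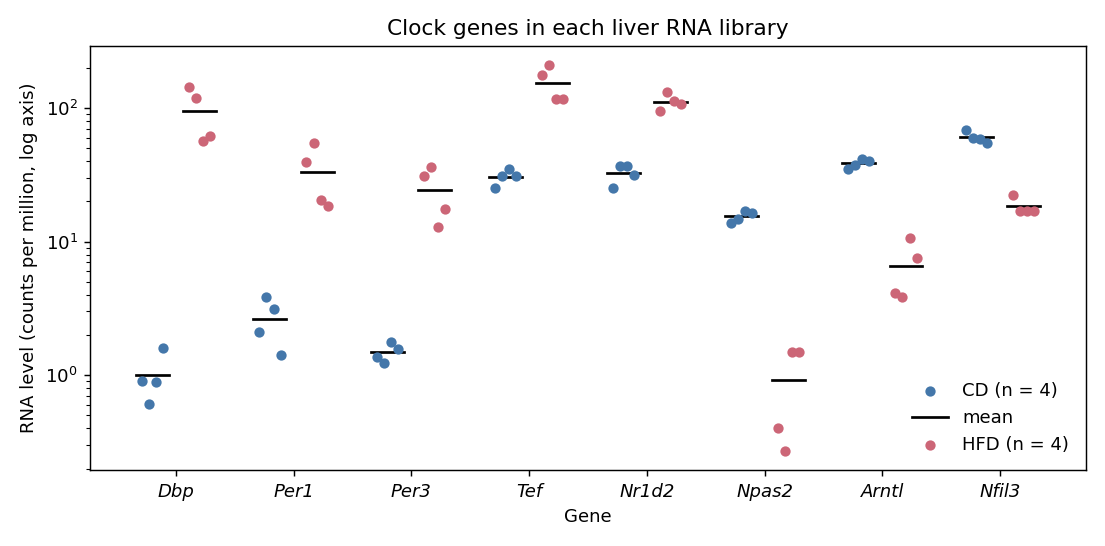
RNA level (CPM, log axis) of 8 clock genes in each of the 4 CD and 4 HFD libraries; points are libraries and bars are group means. Dbp, Per1, Per3, Tef and Nr1d2 were higher in every HFD library than in every CD library, and Npas2, Arntl and Nfil3 lower.

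Of 16 genes known for higher expression in male than in female mouse liver 10 fell, 0 rose and 6 did not pass. Adjusted over the list alone 11 fell. Elovl3, a fatty acid elongase, fell from 877 ± 78.4 to 180 ± 70.4 CPM (SD, n = 4, log2 change -2.28, SE 0.24, adjusted p = 0.000422), and the P450 Cyp4a12a from 452 ± 45 to 101 ± 39.3 CPM (log2 change -2.17, SE 0.23, adjusted p = 0.000422). Its close relative Cyp4a12b had a log2 change of -2.08 (SE 0.22). Of 18 genes known for the opposite 9 were measured, of which 6 rose and 3 did not pass, and 7 rose when adjusted over the list alone. Cyp17a1, a steroid hydroxylase, rose from 2.51 ± 0.378 to 25.4 ± 8.59 CPM (log2 change 3.34, SE 0.25, adjusted p = 7.05e-05), Atp6v0d2 by log2 1.86 (SE 0.23) and Cyp2a4 by log2 2.66 (SE 0.39). Median log2 changes were -0.96 for the male-biased list (camera adjusted p = 1.06e-10, and adjusted p = 0.118 with an estimated correlation) and 2.11 for the female-biased list (camera adjusted p = 6.55e-08, and adjusted p = 0.118 with an estimated correlation). The median of 2.11 was the same with Cyp2b9 at the lower bound of its counting interval. It could not have changed, since Cyp2b9 stayed far above the median there. The mean of the female-biased list, which Cyp2b9 does move, was 2.83.

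**Figure D2:**
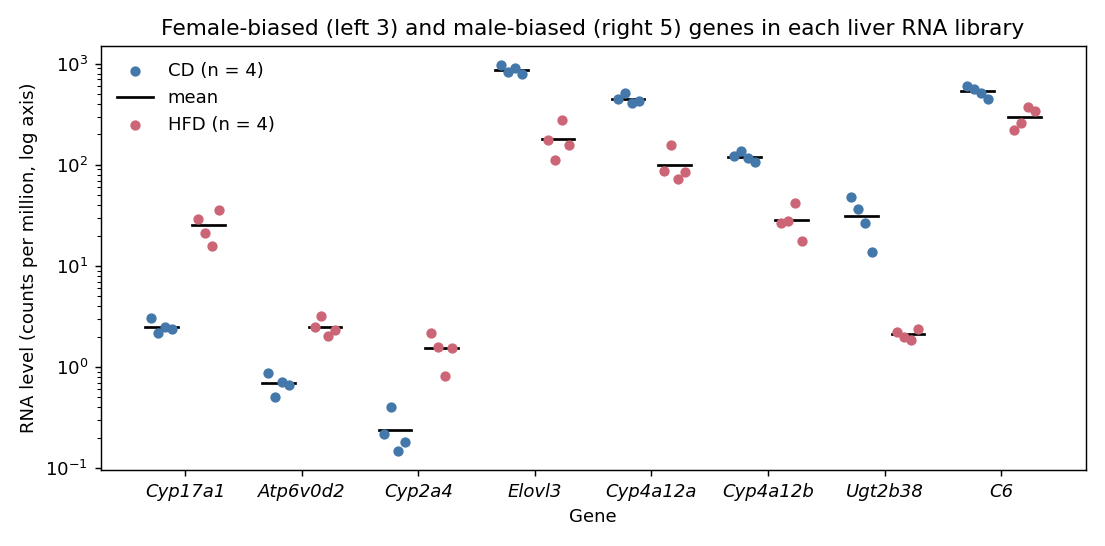
RNA level (CPM, log axis) of 3 female-biased and 5 male-biased genes in each of the 4 CD and 4 HFD libraries; points are libraries and bars are group means. Cyp17a1, Atp6v0d2 and Cyp2a4 were higher in every HFD library, and Elovl3, Cyp4a12a, Cyp4a12b, Ugt2b38 and C6 lower.

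Of 24 cholesterol synthesis genes 14 fell, 0 rose and 10 did not pass. Adjusted over the list alone 16 fell. Hmgcs1, which makes the HMG-CoA used for cholesterol, fell from 731 ± 68.7 to 282 ± 84.2 CPM (SD, n = 4, log2 change -1.38, SE 0.2, adjusted p = 0.00237), Cyp51 from 292 ± 36.6 to 112 ± 34.8 CPM (log2 change -1.39, SE 0.21, adjusted p = 0.00311), Pmvk by log2 change -1.31 (SE 0.22) and Idi1 by -1.61 (SE 0.28). The median log2 change was -0.81 (camera adjusted p = 4.14e-10, and adjusted p = 0.384 with an estimated correlation). Among 20 bile acid and sterol transport genes 5 rose and 4 fell (7 and 4 adjusted over the list alone). Abcg5 and Abcg8, whose products together export sterols into bile, rose from 44.4 to 151 CPM (log2 change 1.77, SE 0.17) and from 74.3 to 209 CPM. Akr1d1 rose by log2 0.81 (SE 0.1). Cyp8b1, which directs bile acid synthesis towards cholic acid, fell from 444 ± 76.1 to 157 ± 34.7 CPM (log2 change -1.50, SE 0.18, adjusted p = 0.000753). The other called members, named after their values had been seen, were Slco1a4 (1.35) and Slc10a1 (0.52) among those that rose, and Cyp7b1 (-1.08), Abcc3 (-0.65) and Cyp27a1 (-0.41) among those that fell. The highest adjusted p with a library left out was 0.082 for Slc10a1 (without HFD B), 0.102 for Cyp7b1 (without HFD B), 0.0897 for Abcc3 (without CD C) and 0.0978 for Cyp27a1 (without CD A). The bile acid list did not pass with camera (median 0.07, camera adjusted p = 0.145) but did with fry (fry adjusted p = 0.0135).

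Among 21 measured genes of xenobiotic metabolism 3 rose and 7 fell, and adjusted over the list alone 3 rose and 10 fell. Those that rose were Cyp2b9, Cyp2e1 and Cyp2a5 (log2 change 1.44, SE 0.23, adjusted p = 0.00453), the last named after its values had been seen. Beside Cyp3a11, Cyp2c29 fell from 2128 ± 138 to 865 ± 130 CPM (SD, n = 4, log2 change -1.30, SE 0.12, adjusted p = 0.000224) and Cyp2c55 by a log2 change of -2.20 (SE 0.2). The list had a median of -0.08 (camera adjusted p = 0.0484, and adjusted p = 0.749 with an estimated correlation), with adjusted p = 0.239 without HFD D, 0.0906 without HFD C, 0.0552 without CD A, 0.0657 without CD B and 0.0598 without CD D. Of 19 glutathione and antioxidant genes 4 fell and 0 rose, over all genes and adjusted over the list alone: Gstm3 (log2 change -1.76, SE 0.22), Gstp1 (-1.08, SE 0.17), Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis (-0.89, SE 0.14), and Gsr (-0.51, SE 0.1). Their list had a median of -0.13 (camera adjusted p = 0.036, and adjusted p = 0.749 with an estimated correlation), with 0.142 without HFD D, 0.0935 without HFD C, 0.0617 without CD B and 0.088 without CD D.

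Genes of glucose and insulin signalling rose more often than they fell: 8 rose and 2 fell among 19 (12 and 2 adjusted over the list alone). Slc2a2, the main hepatic glucose transporter, rose from 269 ± 33.8 to 462 ± 41.5 CPM (SD, n = 4, log2 change 0.78, SE 0.12, adjusted p = 0.00267) and Sds, a serine dehydratase, by log2 1.76 (SE 0.32). Igfbp1, a secreted binding protein that insulin represses, fell from 93.8 ± 30.9 to 16.1 ± 4.10 CPM (log2 change -2.54, SE 0.27, adjusted p = 0.000498). Irs2, an insulin receptor substrate named after its values had been seen, fell by a log2 change of -1.72 (adjusted p = 0.018, with 0.0595 without CD B, 0.0577 without HFD B and 0.0516 without CD A). The list median was 0.52 (camera adjusted p = 0.000183, and adjusted p = 0.26 with an estimated correlation). In fatty acid oxidation and ketogenesis 4 of 28 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.165). The nuclear receptor Ppara rose by log2 0.98 (SE 0.13) and Cpt1a, which admits fatty acids to mitochondria, by 0.89 (SE 0.12), while Pdk4 and Acot1 fell, the latter by -0.92 (SE 0.15). Acadl (0.44), Vnn1 (0.59) and Pex11a (-0.54), named after their values had been seen, reached an adjusted p of 0.0891 without HFD B, 0.121 without CD A and 0.0902 without CD B.

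In de novo lipogenesis 3 of 20 rose and 0 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.258). The desaturases Fads2 and Fads1 rose by log2 1.27 (SE 0.18) and 0.76 (SE 0.14), and Srebf1, a regulator of lipid synthesis, by 1.27 (SE 0.26, adjusted p = 0.0144, and 0.0508 without HFD B). Me1 did not pass (log2 change -0.84, adjusted p = 0.064). Of 21 lipid droplet genes 4 rose and 3 fell (4 and 4 adjusted over the list alone, median -0.14, camera adjusted p = 0.771). Apoa4 rose from 192 ± 32.7 to 725 ± 137 CPM (SD, n = 4, log2 change 1.91, SE 0.16, adjusted p = 0.000127), Vldlr by log2 1.94 (SE 0.29) and Cd36, a fatty acid receptor, by 0.84 (SE 0.16). Cidec fell (log2 change -1.45, SE 0.32, adjusted p = 0.0212), but its call was lost without CD B (0.067), CD C (0.0637), HFD B (0.0771), HFD C (0.0557) and HFD D (0.0503). Dgat2 (0.6), Pparg (-1.11) and Lpl (-0.82), named after their values had been seen, reached an adjusted p of 0.0898 without HFD B, 0.0679 without HFD B and 0.123 without HFD B.

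Of 12 immediate early genes 6 fell and 0 rose (8 fell adjusted over the list alone), with a median log2 change of -1 (camera adjusted p = 2.59e-06, and adjusted p = 0.118 with an estimated correlation). Jun fell from 32.5 ± 9.27 to 9.86 ± 1.35 CPM (SD, n = 4, log2 change -1.72, SE 0.19, adjusted p = 0.000609) and Myc by a log2 change of -2.62 (SE 0.54). Fos fell as well (-1.91, SE 0.42, adjusted p = 0.0198), with adjusted p = 0.0521 without CD B and 0.0533 without HFD C. Of 18 genes of the endoplasmic reticulum stress response 7 fell and 0 rose (2 rose and 9 fell adjusted over the list alone), with a median of -0.44 (camera adjusted p = 0.00226, and adjusted p = 0.384 with an estimated correlation). Asns, the asparagine synthetase, had a log2 change of -2.26 (SE 0.43) and Sdf2l1, a chaperone, of -1.16 (SE 0.22). Creld2 (-1.15, SE 0.26, adjusted p = 0.0246) was lost without CD B (0.0624), CD C (0.0627), HFD B (0.0873) and HFD D (0.0604), and Pdia6 (-0.46, SE 0.1, adjusted p = 0.0254) without CD A (0.0825), CD B (0.0596), CD C (0.0698) and HFD B (0.0858).

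Of 19 acute phase genes 3 rose and 2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.0619). Serpina3n rose by log2 0.83 (SE 0.13, adjusted p = 0.00345), Saa4 by 0.55 (SE 0.11, adjusted p = 0.0144, with 0.0519 without CD B and 0.0555 without CD C) and the metallothionein gene Mt2 by 1.56 (SE 0.38, adjusted p = 0.0333, with 0.0919 without CD A, 0.0938 without CD B, 0.08 without CD C, 0.104 without HFD B and 0.069 without HFD D). The fibrinogen genes Fga and Fgg fell by log2 changes of -0.53 (adjusted p = 0.0263, with 0.0769 without CD A, 0.0759 without CD B and 0.0909 without HFD B) and -0.49 (adjusted p = 0.0387, with 0.129 without HFD B), Fgg named after its values had been seen. Among 20 complement and coagulation genes 0 rose and 2 fell (1 and 3 adjusted over the list alone), C8b (log2 change -0.87, SE 0.15) and C6 (-0.84, SE 0.17, adjusted p = 0.0519 without HFD B). The list median was 0.06 and its mean -0.05, with the test downward (camera adjusted p = 0.977). Among 13 cytokine and NF-kB target genes 1 rose, Il1rn (log2 change 1.44, SE 0.29, list camera adjusted p = 0.124), and of 7 MHC class II genes 0 passed (camera adjusted p = 0.292). Of 20 interferon response genes 1 rose (5 adjusted over the list alone), Gbp3 (log2 change 1.14, SE 0.25, adjusted p = 0.0187, with 0.0512 without CD B, 0.0609 without CD C and 0.0517 without CD D). Gbp2 (1.58, adjusted p = 0.0504) and Cxcl9 (1.69, adjusted p = 0.0645) did not pass. The interferon list had a median of 0.26 (camera adjusted p = 0.0312, and adjusted p = 0.749 with an estimated correlation), and adjusted p = 0.139 without HFD D, 0.0719 without HFD C and 0.0902 without CD C. Relative to the CD mean, HFD D had the highest mean log2 level of the interferon (0.88), MHC class II (1.14), cytokine (0.99) and macrophage (0.77) lists.

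Markers of cell types other than hepatocytes differed between single HFD livers. Relative to the CD mean, the mean log2 level of 12 sinusoidal endothelium markers was -0.57, -0.28, 0.62 and 0.55 in HFD A to D, and that of 14 Kupffer cell and macrophage markers -0.7, -0.05, 0.18 and 0.77. Neither list had a member past the threshold (0 of 12 and 0 of 14, camera adjusted p = 0.612 and 0.771). The same held for 6 lymphocyte markers (0 of 6, adjusted p = 0.635). Of 7 cholangiocyte markers 1 fell, Sox9 (log2 change -1.45, SE 0.27, adjusted p = 0.00987), and 2 fell adjusted over the list alone. The median was -0.77 (camera adjusted p = 0.000977, and adjusted p = 0.19 with an estimated correlation). Stellate cell markers had 0 of 13 past the threshold and a median of -0.26 (camera adjusted p = 0.0416, and adjusted p = 0.749 with an estimated correlation), with 0.317 without HFD A, 0.142 without HFD B, 0.101 without CD B and 0.0566 without CD A. Their mean log2 level was -0.79, -0.63, -0.04 and 0.23 in HFD A to D, and -0.2 to 0.19 under CD. HFD A and B (heading numbers 435 and 437) lay below HFD C and D (496 and 505) in the stellate and endothelial markers.

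Among hepatocyte markers 0 of 13 passed, with a median of 0.23 (camera adjusted p = 0.0484, and adjusted p = 0.749 with an estimated correlation), and 0.181 without HFD A, 0.0948 without HFD B, 0.101 without CD B and 0.0965 without CD C. Of 11 genes of hepatocytes near the central vein 5 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0559, fry adjusted p = 0.0018). Oat rose from 435 ± 96.5 to 1013 ± 70.9 CPM (SD, n = 4, log2 change 1.22, SE 0.15, adjusted p = 0.000916), Lect2 by log2 1.21 (SE 0.15), Slc1a2 by 0.92 (SE 0.16) and Cyp2e1 by 0.61 (SE 0.12, adjusted p = 0.0544 without HFD B). Glul rose (0.48, adjusted p = 0.0737 without HFD B) and Cyp27a1 fell, both named after their values had been seen. Of 11 genes of hepatocytes near the portal vein 2 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.09). Cdh1 (log2 change -0.71, SE 0.1) and Cyp2f2 (-0.66, SE 0.13) fell, and Sds and Pck1 rose, the latter by 1.04 (SE 0.28, adjusted p = 0.047, with 0.162 without HFD B, 0.128 without CD C, 0.121 without CD D, 0.104 without CD A, 0.0794 without HFD A and 0.0549 without CD B). The call of Pck1 was also lost with library totals (adjusted p = 0.0523) and with a filter at the median level (0.0573). Ribosomal protein genes had 0 of 31 past the threshold and a median of -0.17 (camera adjusted p = 0.00089, and adjusted p = 0.749 with an estimated correlation, and 0.103 without HFD D). Relative to the CD mean, their mean log2 level was 0.16, -0.19, -0.31 and -0.46 in HFD A to D, and -0.16 to 0.17 under CD. Oxidative phosphorylation (0 of 28, adjusted p = 0.0677) and cell cycle genes (0 of 14, adjusted p = 0.292) did not pass. Of 28 enzymes that add or remove histone acetyl groups Hdac11 rose (log2 change 0.59, SE 0.1) and Hdac5 fell (-0.64, SE 0.13, list median -0.04, mean 0, camera adjusted p = 0.744). Neutrophil and adipocyte lists had 1 measured gene each, which did not pass, the erythroid list 2, of which Slc4a1 fell (log2 change -1.30, adjusted p = 0.0266, with 0.0845 without CD B, 0.0697 without CD D and 0.0898 without HFD B). The exocrine pancreas list had 1, Cela1, which rose (0.84, SE 0.16). These 4 lists were too small to test.

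**Figure D3:**
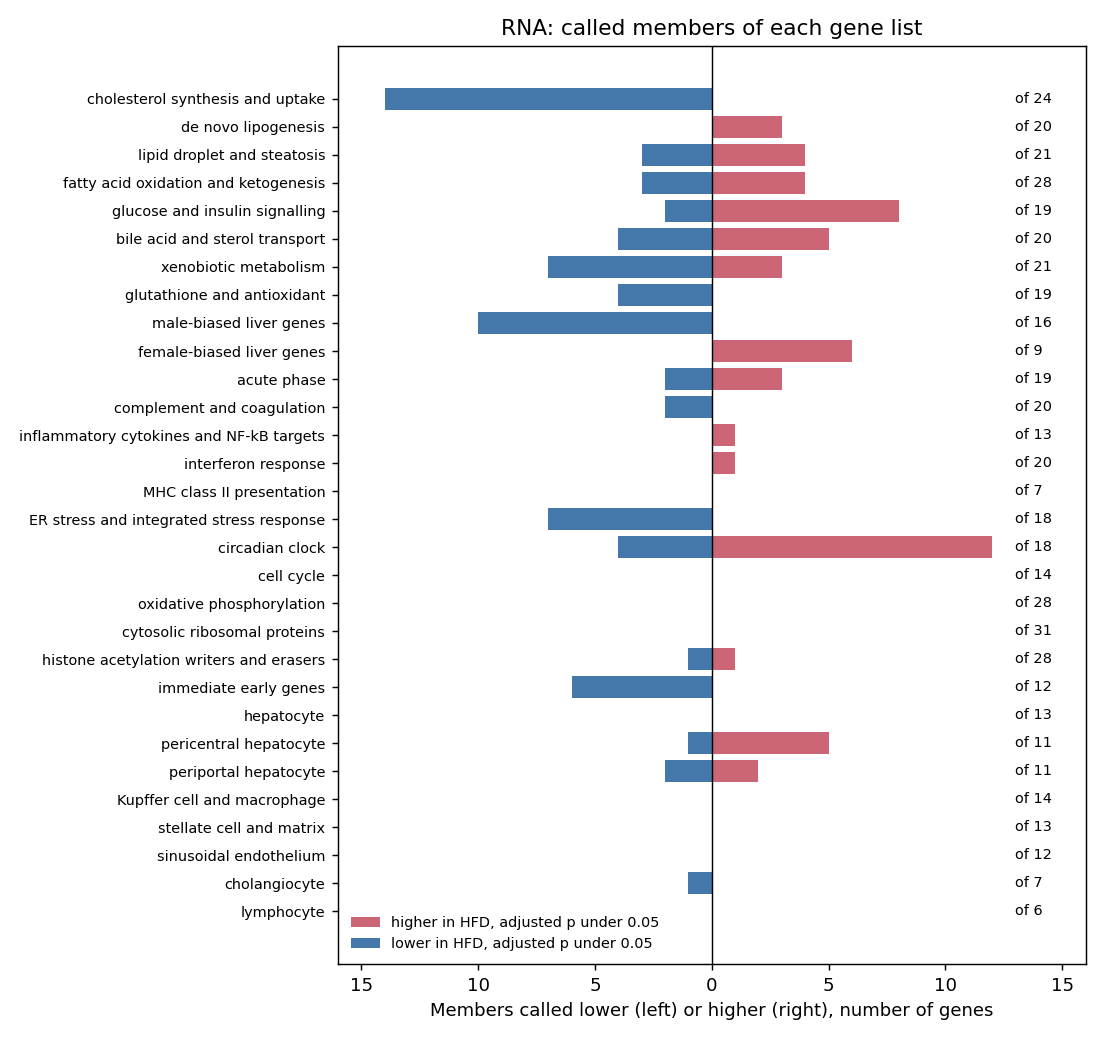
Number of members of each tested gene list with RNA past the threshold (adjusted p under 0.05), higher in HFD to the right and lower to the left, with the number measured beside each bar. The clock list had 12 higher and 4 lower of 18, and cholesterol synthesis 14 lower of 24.

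Of 34 lists, 30 were tested in the RNA, and 14 passed with camera (5 higher and 9 lower). With an estimated correlation 0 passed, and with fry, which tests whether a list's genes move on balance in one direction, 10 did. Those 10 included the bile acid and central vein lists, which did not pass with camera. Other divisions of the 8 libraries into 4 and 4 called up to 16 lists, so the number of lists called could have arisen by chance.

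The largest H3K9ac increases among the regions named were at the microRNA gene Mir802, and the largest decreases at Csad and Selenbp2. The Mir802 region at chromosome 16, 93368282 to 93369210, within 1000 bases of the start site, rose from 2.51 ± 0.563 to 19.4 ± 4.62 CPM (SD, n = 3 per diet, log2 change 2.96, SE 0.2, adjusted p = 1.7e-17), and its neighbour at 93369393 to 93370562 by log2 2.53 (SE 0.22). A region of Csad at chromosome 15, 102186472 to 102189295, fell from 75.6 ± 8.60 to 13.3 ± 1.70 CPM (log2 change -2.50, SE 0.11, adjusted p = 3.1e-26). Csad lies on the minus strand, and this region spans its start at 102189043. It was classed as intronic because its listed distance was 1159 bases. The promoter-proximal region of Npas2 at chromosome 1, 39192274 to 39194770, fell from 116 ± 10.6 to 29.1 ± 3.24 CPM (log2 change -2.01, SE 0.09, adjusted p = 1.32e-25).

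Further increases lay in introns of Ccrn4l (chromosome 3, 51225978 to 51226705, log2 change 1.96, SE 0.23) and Cyp17a1 (chromosome 19, 46670384 to 46672155, 1.82, SE 0.21). Another lay in an intron at -67003 bases from the start site of Pdcd4, its nearest gene (chromosome 19, 53824824 to 53825631, 1.78, SE 0.26). A region inside the gene Rgs16 also rose (chromosome 1, 153741816 to 153742415, 1.77, SE 0.19). Further decreases lay upstream of Selenbp2 (chromosome 3, 94682296 to 94683617, log2 change -2.34, SE 0.26) and in an intronic region of Csad (-2.20, SE 0.26). Others lay at the start of Serpina1e (chromosome 12, 103956395 to 103956980, -1.96, SE 0.25) and in an intron of Asap2 (chromosome 12, 21167591 to 21168261, -1.89, SE 0.23).

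By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1372 of 57499 regions passed, 480 higher and 892 lower in HFD, and 350 of them differed at least 2-fold. Of the 1372, 1255 had diets that did not overlap, against 8860 of all regions (15.4%, 10% by chance). By position 204 higher and 378 lower regions lay in introns, 166 and 211 within 1000 bases of a start site, 8 and 19 in untranslated regions, 38 and 89 elsewhere within 10 kb of a gene start, and 64 and 195 elsewhere. The count was 563 without HFD B (188 higher and 375 lower), 827 without CD C, 871 without HFD A, 813 with DESeq2 and 887 with a filter at the median level. Without HFD D it was 1862, 852 higher and 1010 lower. The authors' deposited values called 1382 regions, 495 higher and 887 lower, of which 1264 were among the 1372.

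Promoter-proximal H3K9ac of clock genes moved in both directions: 5 of 14 members rose and 4 fell (7 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.477). The region of Per3 at chromosome 4, 151043365 to 151045289, rose from 43.3 ± 2.65 to 99.8 ± 5.90 CPM (SD, n = 3, log2 change 1.21, SE 0.09, adjusted p = 1.25e-16), those of Tef and Hlf by log2 0.68 (SE 0.08) and 0.77 (SE 0.11), that of Ciart by 1.47 (SE 0.13) and that of Per1 by 0.41 (SE 0.09, adjusted p = 0.0545 without HFD A). Beside Npas2, those of Arntl (-0.95, SE 0.08), Clock (-0.5, SE 0.07) and Nfil3 (-0.38, SE 0.08, adjusted p = 0.0519 without CD C) fell. Ciart, Hlf, Arntl and Clock were named after their values had been seen, and Clock did not pass in the RNA (-0.61, adjusted p = 0.197).

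Of 18 cholesterol synthesis genes 4 fell and 0 rose (6 fell adjusted over the list alone), with a median of -0.14 (camera adjusted p = 4.32e-07, and adjusted p = 0.558 with an estimated correlation). Promoter-proximal H3K9ac of Cyp51 fell by a log2 change of -0.49 (n = 3 per diet, SE 0.08, adjusted p = 2.53e-05), of Sqle by -0.91 (SE 0.11), of Pmvk by -0.41 (SE 0.11, adjusted p = 0.0358, with 0.279 without CD C, 0.27 without HFD B, 0.114 without HFD D and 0.11 without CD A) and of Tm7sf2 by -0.32 (adjusted p = 0.0269, with 0.214 without CD C, 0.203 without HFD B, 0.0779 without HFD A and 0.0561 without CD A). Sqle and Tm7sf2 were named after their values had been seen. Of 8 male-biased genes 4 fell and 0 rose (5 fell adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.000321, and adjusted p = 0.558 with an estimated correlation). They were Serpina1e, Selenbp2 (-1.04, adjusted p = 0.117 without CD A), Susd4 (-0.55, adjusted p = 0.112 without HFD B) and Cyp2d9 (-0.38, adjusted p = 0.205 without HFD D), the last 2 named after their values had been seen. Oxidative phosphorylation genes had 0 of 23 past the threshold and a median of 0.09 (camera adjusted p = 0.0032, and adjusted p = 0.558 with an estimated correlation), with 0.0727 without HFD A and 0.0513 without HFD B. Cell cycle genes had 1 of 14 higher, Birc5 (log2 change 0.34, SE 0.08, adjusted p = 0.00656, with 0.112 without HFD A), and a median of 0.13 (camera adjusted p = 0.0348, and adjusted p = 0.558 with an estimated correlation), with 0.21 without CD C, 0.199 without HFD B and 0.0619 without HFD D. The other lists among the 29 tested did not pass, and in 6 of them the median, mean and test differed in sign, all with camera adjusted p of 0.544 or more. With fry, 0 lists passed in the H3K9ac.

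Regions within 1000 bases of a start site by the authors' distances made up 27.5% of changed and 24% of unchanged regions (377 of 1372 changed regions, odds ratio 1.20, interval 1.06 to 1.36, Fisher's exact p = 0.00294). By these distances a long region that spans a start site, such as that of Csad, can count as farther away. How far this affects the shares was not tested. They were 34.6% of the regions that rose and 23.7% of those that fell. The share was no larger within 500 bases (odds ratio 0.983, exact p = 0.838), and at an unadjusted p under 0.01 the odds ratio was 1.05 (exact p = 0.243). It was 1.14 without CD C (exact p = 0.093) and 1.09 without HFD A (exact p = 0.299). In 4 equal groups of regions by mean H3K9ac signal, 5.02, 6.83, 14.8 and 69.5% of regions were promoter-proximal from the lowest to the highest group. The odds ratios in these groups were 0.902, 0.449, 0.489 and 0.33. Combined over these groups, with n = 57499 regions, the odds ratio was 0.364 (interval 0.317 to 0.417, Mantel-Haenszel p = 6.57e-52). This comparison was added after the data had been seen. Regions are not independent replicates, so the p-values and intervals of these odds ratios do not cover the spread between livers.

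Genes with more RNA had more H3K9ac counts in their promoter-proximal region, up to the upper part of the range. RNA levels were divided by exon length here, but H3K9ac counts were not divided by region length. Longer regions can hold more counts, and the part of region length in this relation was not tested. Across 10112 genes measured in both assays, the Spearman correlation of levels was 0.415 in CD and 0.413 in HFD (Pearson 0.37 and 0.365). The median log2 CPM of H3K9ac was 3.89 in the lowest of 10 equal groups of genes by RNA level, 5.95 in group 5, 6.26 in group 9 and 6.15 in the highest. Genes with a promoter-proximal region had a median of 2.45 log2 FPKM, against 2.11 in those without one.

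**Figure D4:**
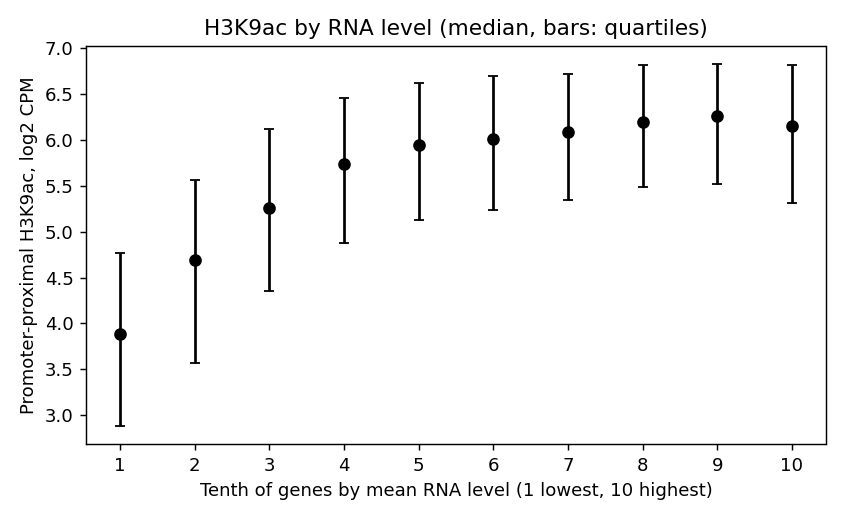
Promoter-proximal H3K9ac (log2 CPM) of genes in 10 equal groups by mean RNA level; points are medians and bars the quartiles. Medians went from 3.89 in group 1 to 6.26 in group 9.

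H3K9ac and RNA changed in the same direction at 99.4% of the 158 genes past the threshold in both. Slc34a2, a phosphate transporter, fell in RNA from 5.55 ± 0.722 to 0.203 ± 0.129 CPM (SD, n = 4, log2 change -4.76, SE 0.31) and in H3K9ac from 25.3 ± 5.89 to 10.5 ± 0.55 CPM (SD, n = 3, -1.27, SE 0.15, adjusted p = 4.87e-09). Fam222a fell by log2 changes of -2.44 (SE 0.17) in RNA and -1.03 (SE 0.09) in H3K9ac, Lrfn3 by -1.57 and -0.75, and Zfp810 by -1.49 and -0.6. Tef, a clock-controlled transcription factor related to Dbp, rose by 2.34 and 0.68. Hamp2 rose by 3.87 and 1.81 (SE 0.35), and Cyp17a1 by 3.34 and 1.25 (SE 0.24). Hamp, in contrast to Hamp2, fell by log2 changes of -1.37 and -0.79 (SE 0.16).

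**Figure D5:**
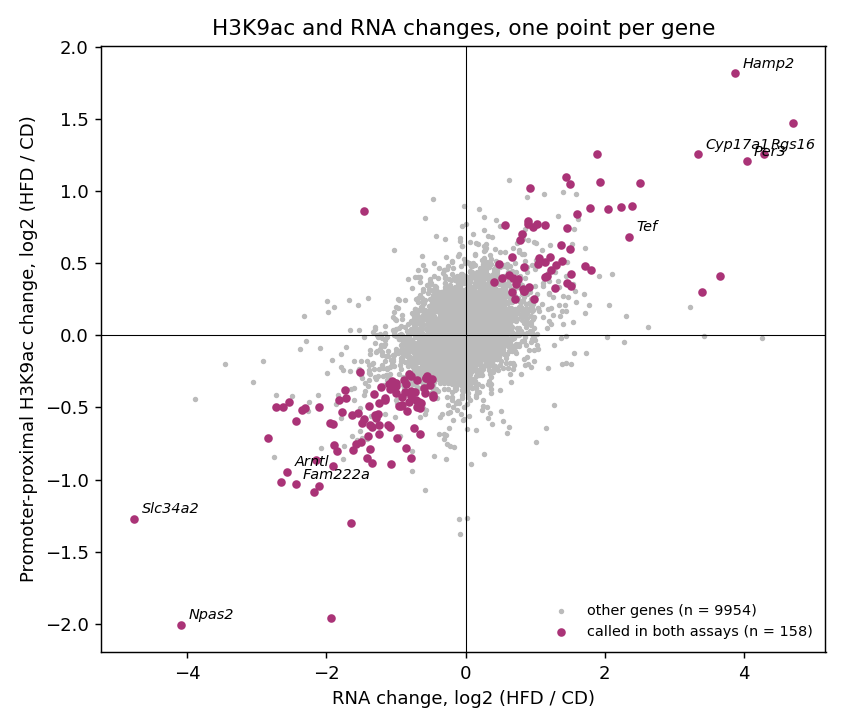
Change of RNA (log2 of HFD over CD, horizontal) against change of promoter-proximal H3K9ac (vertical), 1 point per gene, with the 158 genes past the threshold in both assays in colour. Of these 99.4% had the same direction in both.

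Of 334 genes with higher and 352 with lower RNA among the 10112, 61 also had higher H3K9ac (4.9 if independent, odds ratio 25.1, interval 17.4 to 36.2, Fisher's exact p = 2.12e-52) and 96 lower H3K9ac (6.4 if independent, odds ratio 41.6, interval 30 to 57.8, exact p = 5.94e-94). Opposite directions were found at 0 genes with higher RNA (6 if independent) and 1 with lower RNA (5.1 if independent). Genes are not independent replicates, so these p-values and intervals do not cover the spread between livers. Across all 10112 genes the Spearman correlation of the changes was 0.338 (Pearson 0.478), and 61% had the same sign. Among 686 genes called in the RNA it was 0.748, with 83.1% of the same sign. With only the RNA libraries whose diet and letter had no H3K9ac library, 1 per diet (HFD C and CD B), the correlation was 0.232. With 1 library per diet in each assay, of the same diet and letter, it was 0.176 to 0.313.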

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

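In the groups of 4 RNA libraries, a library was marked when its value for a named gene lay far from the other 3, by Dixon's test at the 95% level. This marked 22 of 248 groups, where about 1 in 20 is marked by chance (12.4 expected), and 12 of the 22 lay under CD, 4 in HFD D, 3 in HFD B, 2 in HFD A and 1 in HFD C. The divisions of the libraries were planned before the data were examined, while the tests of the clock, sex-biased and promoter patterns below were chosen after those results had been seen.

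Under CD, library A stood apart in Fabp5 (70.1 CPM, against 24.4 to 30.9 in the others), Abcg5 (35.7, against 46.1 to 48.2) and Abcg8 (63.7, against 76.9 to 79.3). Library B did so in Usp2 (4.05, against 2.34 to 2.42), Gclc (867, against 579 to 616), Pptc7 (18.3, against 15.5 to 15.9), Agxt (107, against 197 to 215) and Fkbp5 (23.7, against 19.2 to 19.7). Library C did so in Slco1a4 (30.5, against 14.9 to 17.4), and library D in Rgs16 (14.8, against 0.346 to 2.27) and Lpl (23.3, against 36.2 to 38.5). Cyp2b9 was marked in library C as well (0, against 0.027 to 0.031), but each CD library held 0 or 1 count of it, below the floor of 3, so no difference can be read from this.

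Under HFD, library A stood apart in Nfil3 (22.4 CPM, against 16.9 to 17.1) and Apoa4 (928, against 632 to 678). Library B did so in Cyp4a12a (159, against 72.6 to 86.5), Slc2a2 (523, against 435 to 449) and Pdia6 (193, against 235 to 239), and library C in Cyp7b1 (367, against 170 to 189). Library D did so in Gbp2 (23.1, against 5.49 to 7.59), Cxcl9 (62.8, against 12.3 to 16.8), Cyp2e1 (7607, against 8880 to 9131) and Slc34a2 (0.395, against 0.122 to 0.151).

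Every division of the 8 RNA libraries into 4 and 4 was tried, 35 in all. For the number of genes 1 division, the real one, reached 897, and the highest other called 0. That share is the smallest that 35 divisions can give and lay under 0.05, so a chance division is unlikely to account for the number. The correlation of H3K9ac and RNA changes was also highest in the real division (1 of 35, real value 0.338, highest other 0.323). The share was again under 0.05, but chance was not excluded with certainty. The H3K9ac change was kept at its real groups in every division, and the sign of the correlation was ignored. Divisions that exchanged only 1 library per diet kept part of the diet difference, so the small margin to them does not measure chance. The value of 0.323 came from such a division, which exchanged CD C and HFD C. Where each group held as many CD as HFD libraries, the highest value was 0.105. Livers shared between the assays, which the labels do not state, were not excluded as a part of the correlation. Chance cannot be excluded for the number of RNA gene lists (9 of 35 reached the real value of 14, highest other 16). The 10 divisions of the H3K9ac libraries are too few for a share under 0.05: 1 reached 1372 regions (highest other 3), 8 reached 4 lists (highest other 11), and 3 reached the promoter odds ratio of 1.20 (highest finite other 1.58).

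The clock genes were weighed first. A few livers with a shifted clock could not account for the change: over all 18 members of the list, called or not, the mean log2 level relative to the CD mean was 1.23, 1.24, 1.09 and 1 in HFD A to D and at most 0.17 under CD, a gap of 0.83 (SD of the CD libraries 0.17). All 16 called members already had diets that did not overlap, so a gap was likely beforehand. The mean joins genes that rose and fell, and hides differences among HFD livers. Dbp was at 143, 118, 56.9 and 62.2 CPM in HFD A to D, and Npas2 at 0.402, 0.271, 1.49 and 1.49. Nr1d2, at 95.5, 131, 113 and 107 CPM, did not divide A and B from C and D. A difference in circadian phase at collection, from the hour or from feeding, remains possible: 16 of 16 called clock genes moved in the direction that a shifted phase predicts from their known peak times, assigned by hand after their values had been seen. An effect of the diet on the clock predicts the same, and the labels give no collection time, so the data cannot tell these apart.

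The sex-biased genes were weighed second. Livers of different sex were excluded for the RNA, because 4 Y-linked genes summed to between 133 CPM (CD A) and 200 CPM (HFD C) in all RNA libraries (lowest over highest 0.663). The H3K9ac libraries were not checked in this way. Reads shared between near-identical copies could not account for all of the RNA pattern: 7 of 12 members without such a copy were called in the direction of their list. An effect of the diet is possible and was not separated from a difference in circadian phase.

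The larger share of promoter-proximal regions among changed H3K9ac regions was weighed last. More reads at these regions, which make a change easier to detect, may account for it: combined over 4 equal groups of regions by mean signal the odds ratio was 0.364. No biological explanation was tested.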

How the results depend on the processing

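The alternatives were chosen before the data were examined, except the endothelial term and the groups of like H3K9ac signal, which were chosen after the results had been seen. Of 74 settings of the main results, 45 left the result within a tolerance, 24 moved it further, 3 lost the call and 2 changed its sign. The tolerance was 1.5-fold for a count and 1 SD of the values from single libraries for a correlation. For the promoter odds ratio it was the same direction and call. The 45 are therefore not unchanged values. They include 1862 regions without HFD D, 1107 genes without HFD A, and the letter as a block, which kept 943 of the 1372 regions. The number of RNA genes, 897, became 1405 with DESeq2, 543 with a filter at the median level, where fewer genes were tested, 1585 with the endothelial term and 1346 at adjusted p under 0.1, and lay between 478 (without HFD B) and 1107 (without HFD A) with a library left out. The number of H3K9ac regions, 1372, became 813 with DESeq2, 887 with a filter at the median level and 914 at 1.5-fold or more, and lay between 563 (without HFD B) and 1862 (without HFD D). Lists called fell to 0 in both assays with an estimated correlation, and with a library left out lay between 11 and 15 in the RNA and between 2 and 8 in the H3K9ac. The level correlation was 0.367 (Pearson) and 0.393 (mean over regions). The change correlation was 0.478 (Pearson), 0.232 (RNA libraries without an H3K9ac library) and 0.748 (genes called in the RNA), and 0.292 to 0.347 with a library left out. The promoter odds ratio was 0.983 within 500 bases (interval 0.856 to 1.13, which includes 1), was reversed in groups of like signal (0.364), was 1.05 at unadjusted p under 0.01, and 1.09 to 1.49 with a library left out. The cause was not tested in the other cases.

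Whether letters pair the libraries of the 2 diets was not settled. In the RNA, deviations from the diet means of libraries with the same letter correlated at -0.222 to 0.295 (2 of 4 pairs over 0.1). HFD A correlated best with CD D (0.368). In the H3K9ac the 2 pairs of the same letter gave 0.081 and 0.09, above all pairs of unlike letters (-0.118 to 0.046). For the H3K9ac, letter B occurred only under HFD and letter C only under CD. A fit with the letter as a block therefore took the H3K9ac diet difference from letters A and D alone, and left little to estimate the spread between libraries. With the letter as a block, 826 genes (729 of the 897), 1277 regions (943 of the 1372) and 12 RNA lists were called. Named calls lost under it were Fga (adjusted p = 0.0735), Irs2 (0.0534), Cyp27a1 (0.0581), Acadl (0.0521), Vnn1 (0.0516), Fgg (0.0805), Dgat2 (0.0578) and Lpl (0.0852) in the RNA, and the regions of Cdh1 (0.0824), Gbp3 (0.33), Pmvk (0.187) and Tm7sf2 (0.0966). With library totals, RNA calls lost were Pck1 (0.0523), Pptc7 (0.0517), Hlf (0.0616), Vnn1 (0.0929) and Lpl (0.0649). With a filter at the median level they were Pck1 (0.0573) and Vnn1 (0.0598). Of 109 RNA genes called and followed through the settings, 80 kept their call with every library left out and 98 in all other settings. The same held for 37 and 45 of 53 regions, with 0 reversed. The setting without a filter gave no other value, since the filter removed nothing. The median count was 24 to 32 per region in the H3K9ac and 509 to 585 per gene in the RNA, and whether depth or the number of libraries limits the calls was not tested.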

Other observations

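The hypotheses and genes in this part were chosen after the results had been seen, and the values are given without explanation. H3K9ac changed at several regions of the same gene in one direction: of 931 genes with a changed region, 101 had 3 or more, and in 99 of these all moved the same way. Irf2bp2 had 9 lower regions of 36, Gadd45g 7 lower of 22, Selenbp2 8 lower of 11 and Asap2 6 lower of 12, and Pptc7 had 7 higher of 13. The RNA of Selenbp2 (log2 change -2.11, adjusted p = 0.00361) and Asap2 (-2.15, adjusted p = 0.000609) fell and that of Pptc7 rose (0.53, adjusted p = 0.0213, with 0.0873 without HFD B, 0.0689 without CD A, 0.0681 without CD C and 0.0608 without CD D). Irf2bp2 (-0.57, adjusted p = 0.133) and Gadd45g (-1.84, adjusted p = 0.102) did not pass in the RNA. The call of the promoter-proximal region of Irf2bp2 was lost without CD A (adjusted p = 0.0686), CD C (0.191), HFD A (0.107) and HFD B (0.131), and that of Gadd45g without CD C (0.134), with DESeq2 (0.399) and with a filter at the median level (0.0732).

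Some genes had a changed mark without a change of RNA past the threshold. Fgf21, a hormone made by the liver, had higher promoter-proximal H3K9ac (17.8 ± 4.21 to 34.3 ± 3.90 CPM, SD, n = 3, log2 change 0.95, SE 0.13, adjusted p = 4.14e-07) and an RNA change of -0.47 (adjusted p = 0.567). Agxt had 5 lower regions of 8 and an RNA change of 0.62 (adjusted p = 0.0954), Por 5 higher of 20 (0.56, adjusted p = 0.261) and Fkbp5 4 higher of 20 (-0.08, adjusted p = 0.885). The call of the promoter-proximal region of Por was lost without CD D (adjusted p = 0.361), HFD A (0.186) and HFD B (0.25), with DESeq2 (0.136) and with a filter at the median level (0.121).

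Of 995 changed regions over 1000 bases from a start site by the authors' distances, 780 had a nearest gene tested in the RNA. These can include long regions that span a start site, such as that of Csad. For 282 of these regions (36.2%) the nearest gene was called in the RNA, for 265 of them in the direction of the region (94%). Among 32588 unchanged regions with a tested nearest gene, 11.4% were nearest to a called gene (3717 regions), 2493 of them in the same direction (67.1%). Genes can be nearest to several regions, so these counts are not independent.

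Deviations from the diet mean in RNA and H3K9ac correlated across genes with a mean of 0.135 between libraries of the same diet and letter, against 0.136 in the highest other of 36 assignments.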
